A study of Danio rerio with 18 samples.

How the data were processed

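Messenger RNA was measured in pooled whole brains of zebrafish from crosses of fish heterozygous for the hu3528 allele of mfn2. The labels give 3 genotypes in 6 families, so 18 libraries in all: wild type (WT), heterozygous (Het) and homozygous mutant (Hom), with 6 libraries each. Each library is a pool of 4 brains, from 2 females and 2 males, taken at 4 months of age. Each family came from its own pair of parents and 1 mating, and siblings were moved to a tank per genotype after genotyping at 2.5 months. The 6 libraries of a genotype are therefore separate pools from separate families, and within a family the genotype and the tank differ together. Libraries are named here by genotype as labelled and by family.

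The values used are whole-number counts per gene, deposited as a table of the whole series with no normalization. Per the labels' protocols, polyadenylated RNA was prepared with the NEBNext Ultra kit and sequenced as 150-base read pairs, with 40530508 to 69496372 reads stated per library. Per the submitters' processing notes, the tools were STAR 2.7.0a and featureCounts from Subread 1.5.2 with the genome build GRCz11. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Values of genes that overlap another gene on either strand, or that have a near-identical copy, are uncertain for that reason, including mitochondrial genes, whose reads can be shared with nuclear copies. The table held 32057 genes, and its total counts ran from 21945070 to 42897654 per library. All 18 columns of values were matched to samples by name, and 0 columns of values were left unused.

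Gene symbols came from a table pairing Ensembl gene IDs with symbols, which named 28988 of the IDs. A symbol carried by more than 1 ID is printed with its ID. No genome of the build was at hand, so no coordinates are given. Chromosomes came from the order of rows in the table: 17605 IDs matched by name to genes of the GRCz12tu assembly served as anchors, and an ID was given a chromosome where at least 8 of its 10 nearest anchors shared it. Of the name-matched IDs, 98.6% had the same chromosome by both routes, and mfn2 lay on chromosome 8 by both.

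Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test on counts. The filter was filterByExpr by genotype, with a minimum count of 10 and a minimum total of 15, which left 20353 genes. Scaling was TMM, the model held genotype and family over all 18 libraries, and p-values were adjusted with the Benjamini-Hochberg method within each comparison at a threshold of 0.05. The prior count behind fold changes was 0.125. A standard error (SE) is the log2 fold change divided by the square root of the test's F value. Normalized CPM are CPM computed on the TMM-scaled library size, and group values are mean ± SD over libraries. The direction within a family was taken from log2 of CPM plus 0.5.

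Before the data were examined, 44 gene lists were fixed, for pathways and for cell types that a brain or its dissection can hold. They were tested with fry from limma 3.58.1 on voom values with the same model, adjusted over the 44 lists within a comparison. The fry test asks whether the genes of a list move on balance in 1 direction and does not compare the list with other genes. List members were matched by symbol and, where that failed, after removing a trailing paralog letter or number, a step chosen after the symbol table was seen. A list needed 5 tested members. Camera from limma was run with a preset correlation of 0.01 and with an estimated correlation. The share of counts from the 13 mitochondrially encoded protein-coding genes was compared within families by an exact two-sided permutation test of signs. Fisher's exact test compared the share of changed genes on the chromosome of mfn2, with mfn2 itself left out, with that elsewhere.

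The genes named in the text follow a rule fixed before the data were examined. For each comparison it takes mfn2, the 10 raised and the 10 lowered genes of smallest p that passed, moved the same way in at least 5 families and had a symbol other than a clone name. Where fewer than 5 genes passed, it takes the 5 of smallest p, said not to pass. It adds the 3 members of smallest p from each list that passed and the 5 changed genes nearest to mfn2 on its chromosome. Some genes that the rule takes are not reported here and are left out of the counts of named values and of groups tested for outlying libraries. Genes named outside this rule are said to have been chosen after their values were seen.

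Family was kept as a block because the labels make it a shared mating of 1 pair of parents. As a check, deviations from the genotype means were correlated between libraries: the median r was 0.219 over the 18 same-family pairs and −0.053 over the 90 other pairs, and 3 of the same-family pairs lay below 0.1. No pair of libraries agreed within sampling noise, since the lowest chi-square per degree of freedom over genes with at least 50 counts was 8.27. To describe libraries, log2 of CPM plus 1 was compared with the median of all libraries over 11319 genes with a median CPM of at least 8.

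The gene test was tested on simulated counts drawn from the means of the real libraries, with 200 changed genes per comparison among 20177. The changed genes were picked among those with a mean CPM of at least 1, so recovery at lower counts was not tested. For Hom against WT it recovered 10.4% of genes changed 1.5-fold, 58.2% of genes changed 2-fold and 89.4% of genes changed 4-fold, with 4 calls among 19977 unchanged genes. For Het against WT it recovered 10.4%, 71.6% and 90.9% at those sizes, with 6 calls among unchanged genes. In the simulated Hom against WT data the list test called the 1 changed list, whose members were all raised, and 0 of 40 unchanged lists. Genes were drawn independently, so this does not test false list calls where genes are correlated.

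Alternatives fixed before the data were examined were a fit without family, DESeq2 size factors, DESeq2 1.42.0, limma-voom, no filter, a mean CPM of at least 1, only the compared genotypes, robust dispersion, each family and each library left out, and other list tests. Alternatives chosen after the data were seen leave out 3 libraries that stand apart, leave out those and family 2, weight libraries by quality, scale on nuclear genes alone, or take chromosomes by name alone. A correction for GC content and gene length was not run because no sequence or annotation of the build was at hand, and a share that adds the mitochondrial ribosomal RNA genes was not run because the symbol table does not name them. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.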

Results

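Gene counts were obtained from 18 pools of whole zebrafish brain, 6 each of WT, Het and Hom siblings for a mutant allele of mfn2. This gene encodes mitofusin, a protein of the mitochondrial outer membrane that acts in mitochondrial fusion. Each of the 6 families gave 1 library per genotype. Total counts per library ran from 21945070 in the Hom library of family 3 to 42897654 in the library labelled WT of family 2. After the filter, 20353 genes were tested. The comparisons ask what the brain transcriptome of adult siblings looks like with 1 or 2 mutant copies of mfn2.

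The transcript of mfn2 itself was at 120.2 ± 23.0 normalized CPM in WT, 82.9 ± 18.5 in Het and 29.0 ± 3.22 in Hom (SD, n = 6 each). Its log2 fold change was −2.05 ± 0.17 (SE) for Hom against WT and −1.52 ± 0.17 for Hom against Het, both past edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p of 5.20e-05 and 4.86e-04. In families 1, 3, 4, 5 and 6, Hom levels were 20.4% to 24.3% and Het levels 52.2% to 66.8% of the WT sibling level. Family 2 went against its labels: the library labelled WT was at 75.2 normalized CPM, against 119.9 to 140.2 in the other 5 WT libraries (129 ± 7.30). The library labelled Het was at 117, against 67.8 to 86.4 in the other 5 Het libraries (76.1 ± 8.84). All libraries were kept in their labelled groups, so every direction below that involves WT or Het rests on groups that hold the library labelled WT and the library labelled Het of family 2.

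**Figure D1:**
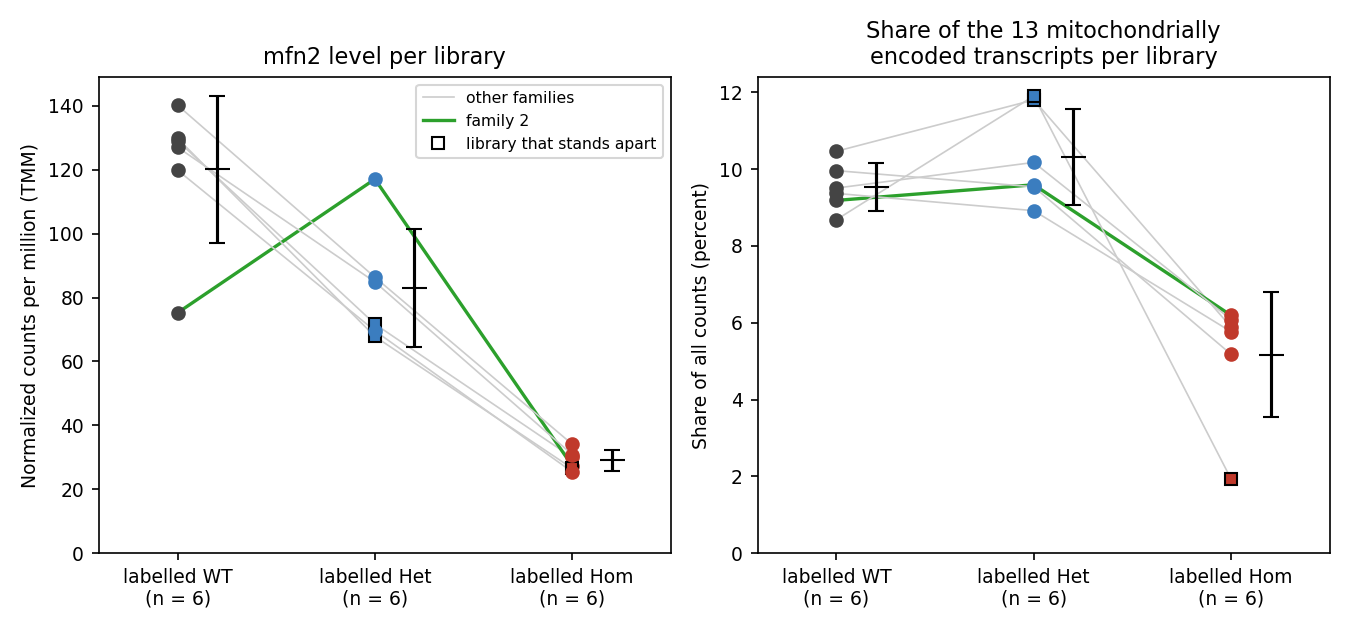
Normalized CPM of mfn2 (left) and percent of all counts from the 13 mitochondrially encoded protein-coding genes (right) in each of the 18 libraries by labelled genotype, with lines joining the libraries of a family, squares for the 3 libraries that stand apart and bars for mean and SD. The Hom libraries lie at 25.4 to 34.1 normalized CPM of mfn2, and the line of family 2 rises from 75.2 in the library labelled WT to 117 in the library labelled Het.

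3 libraries stood apart from the rest in the spread of their log2 deviations from the median library. The SD of these deviations over 11319 genes was 0.697 in the Het library of family 1, 0.643 in the Het library of family 3 and 1.06 in the Hom library of family 3, against 0.183 to 0.279 in the other 15. In these 3 libraries 1772, 1742 and 3238 genes lay more than 2-fold from the median, against 33 to 132 in the others. Across genes, which are not independent replicates, the deviations of both Het libraries correlated with r = 0.88 with each other and with r = −0.65 each with the Hom library of family 3. Pairs among the other 15 libraries had r from −0.33 to 0.67, and pairs of these 3 libraries with the other 15 were not summarized. Transcripts of an oocyte list, written after egg transcripts had been seen in it, summed to 246 CPM in that Hom library and to at most 17.4 CPM in any other. Counts of genes past the test over all genes are given below with and without these 3 libraries, an alternative chosen after the data were seen. So are counts of members for the lists that passed fry with all libraries.

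Single genes that passed between brains of Hom fish and of WT siblings included stress-induced regulators, neurofilaments, enzymes of sterol synthesis and mitochondrially encoded respiratory subunits. Their lists passed the fry test but not camera with an estimated correlation, as given below. Among the raised genes were the stress-induced transcription factor atf3 (log2 fold change 2.54 ± 0.16, from 4.76 to 27.9 normalized CPM) and the stress pseudokinase trib3 (1.65 ± 0.15). The ubiquitin-like interferon-induced gene isg15 was raised as well (3.98 ± 0.27, from 2.13 to 33.7 normalized CPM). Neurofilament transcripts were among the lowered genes, with nefla at −1.80 ± 0.13, from 603 ± 97.3 to 173 ± 39.3 normalized CPM, and nefmb at −2.58 ± 0.24, from 226 ± 65.9 to 37.4 ± 14.7 (n = 6). Enzymes of cholesterol synthesis were lowered too, including lss (−1.57 ± 0.18), sqle (ENSDARG00000079946, −2.21 ± 0.25) and cyp51a1 (−1.53 ± 0.17). The error after ± is the SE for a fold change and the SD for a level. Each gene moved the same way in 6 of 6 families.

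The other raised genes named by the rule were the glucose transporter slc2a1 (ENSDARG00000007412, log2 fold change 1.81 ± 0.14), mych of the Myc family (2.28 ± 0.18), the transglutaminase tgm2l (2.61 ± 0.24), tspan36 (1.53 ± 0.15), the cytokine signalling inhibitor socs3 (ENSDARG00000025428, 2.89 ± 0.28), ush1c (2.45 ± 0.24) and ociad2 (5.96 ± 0.59). The last was near the floor in WT, at 0.147 ± 0.106 normalized CPM against 9.99 ± 4.69 in Hom (n = 6). The other lowered genes included mfn2 itself, the serine protease tmprss4b (−1.40 ± 0.14), the neuronal and muscle elongation factor eef1a2 (−1.05 ± 0.12) and the calcium-binding protein gene cabp5a (−1.25 ± 0.15). Adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 1.99e-05 for atf3 to 7.25e-04 for cabp5a over these genes, and each moved the same way in 6 of 6 families.

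**Figure D2:**
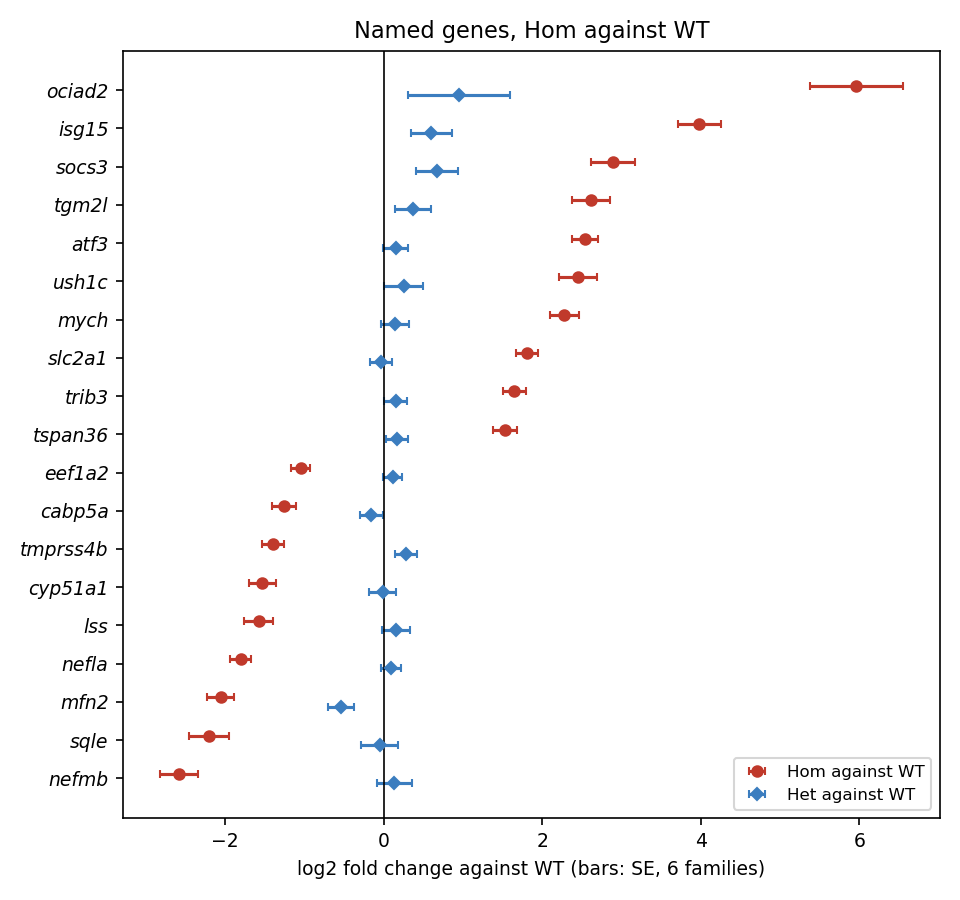
Log2 fold change against WT of named genes, for Hom (circles) and Het (diamonds), with bars for the SE from the fit of all libraries and with groups as labelled. Hom values run from −2.58 for nefmb to 5.96 for ociad2, and the Het value of mfn2 is −0.54.

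In all, 390 of 20353 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment for Hom against WT, 304 higher and 86 lower in Hom. Without the 3 libraries that stand apart, 1658 genes passed, 981 higher and 677 lower, and 388 of the 390 were among them. Leaving out a family gave 190 (family 1), 243 (2), 716 (3), 142 (4), 149 (5) and 216 (6) genes. Leaving out a library moved the count by more than 1.5 times for WT of family 1 (214), 3 (245), 4 (199) and 5 (196), and for Hom of family 3 (706), 4 (209) and 5 (208). The share of higher genes was 77.9% with all libraries, 59.2% without the 3 libraries and 65.3% with DESeq2, which called 1054 genes.

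Of 44 lists, 15 passed the fry test for Hom against WT, 8 higher and 7 lower in Hom. None passed (0 of 44) when camera used an estimated correlation, where the lowest adjusted p was 0.0702. In the fit without the 3 libraries, 5 of the 44 passed with an estimated correlation: p53 targets, neurofilament and axon genes, mitochondrially encoded subunits, interferon response and the stress response list. By fry 19 lists passed without the 3 libraries, 9 higher and 10 lower. Beside the 15, these were pan-neuronal markers, complexes II and III (fry adjusted p = 0.0463), mitochondrial ribosomal proteins (0.0494) and mural and meningeal fibroblast markers (0.0242). The 29 other lists had adjusted p from 0.0645 to 0.970 by fry with all libraries. They included the nuclear-encoded subunits of respiratory complex I (median log2 fold change −0.36, adjusted p = 0.141), complex IV (−0.27, adjusted p = 0.224) and ATP synthase (−0.34, adjusted p = 0.138). Median, mean and test differed in sign for 2 lists, both not called: myelin and oligodendrocyte markers, and photoreceptor and pineal markers.

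Neurofilament and axon genes fell as a list (fry adjusted p = 7.57e-04, median log2 fold change −0.18). Over all genes 5 of 34 members fell and 0 rose, and 7 fell when adjusted over the list alone, with adjusted p = 0.0702 with an estimated correlation. Besides nefla and nefmb, the medium neurofilament chain nefma fell (log2 fold change −0.95 ± 0.12, from a mean of 838 in WT to 433 normalized CPM in Hom). With the 3 libraries left out, 12 members fell, and the adjusted p was 0.00825 with an estimated correlation. GABAergic neuron markers fell as a list (fry adjusted p = 0.00278, median −0.31), with 1 of 22 members past the test over all genes, 5 when adjusted over the list alone and adjusted p = 0.0702 with an estimated correlation. That member was calb2b, a calcium-binding protein gene (−0.86 ± 0.14). The next members, calb2 (−0.46 ± 0.11) and the GABA-synthesizing enzyme gene gad1 (ENSDARG00000027419, −0.31 ± 0.08), did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0590 and 0.0901). Of these, calb2 passed in the fit without the family block (adjusted p = 0.0241). With the 3 libraries left out, 8 of 23 members fell over all genes, and 9 fell and 1 rose when adjusted over the list alone. Pan-neuronal markers had a median of −0.11 and did not pass (fry adjusted p = 0.220). They passed without the 3 libraries (median −0.15, fry adjusted p = 0.00209, adjusted p = 0.0854 with an estimated correlation).

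Genes of cholesterol synthesis and uptake fell as a list (fry adjusted p = 5.11e-04, median log2 fold change −0.61). Over all genes 11 of 33 members fell and 0 rose, and 18 fell when adjusted over the list alone, with adjusted p = 0.0702 with an estimated correlation. Its members included sqle (ENSDARG00000079946) and lss, given above. With the 3 libraries left out, 19 members fell, and the adjusted p was 0.0854 with an estimated correlation.

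All 13 mitochondrially encoded subunits had negative fold changes and fell as a list (fry adjusted p = 0.00240, median log2 fold change −1.06). Over all genes 8 of 13 fell, and 13 fell when adjusted over the list alone, with adjusted p = 0.0934 with an estimated correlation. The members of smallest p were the complex I subunits mt-nd3 (−1.64 ± 0.23) and mt-nd2 (−1.23 ± 0.18) and the complex IV subunit mt-co1 (−1.08 ± 0.18). The Hom library of family 3, which stands apart, had the lowest level of mt-nd3, at 122 normalized CPM against 423 to 508 in the other 5 Hom libraries. Without the 3 libraries all 13 passed over all genes, with a median of −0.83 and adjusted p = 0.0317 with an estimated correlation.

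As a share of all counts, the 13 mitochondrially encoded genes made up 9.53 ± 0.620% in WT, 10.3 ± 1.25% in Het and 5.17 ± 1.63% in Hom (SD, n = 6 each). Hom was lower than WT in 6 of 6 families, with a mean log2 difference of −0.98 ± 0.60 (SD), and lower than Het in 6 of 6, by −1.09 ± 0.77. The exact two-sided permutation test of signs gave p = 0.03125 for each, the smallest p that 6 families allow, and 0.0469 after adjustment over 3 comparisons. The share in Het was higher than in WT in 4 of 6 families by a mean log2 difference of 0.11, which did not pass (exact permutation p = 0.219). The Hom library of family 3 had a share of 1.93%, and without the 3 libraries the Hom share was 5.82 ± 0.396% (n = 5), a difference from WT of −0.74 in 5 of 5 families, for which an exact test cannot give a p below 0.0625.

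Some lists of stress and damage responses rose, and others did not pass. The p53 targets rose as a list (fry adjusted p = 5.11e-04, median log2 fold change 0.40), with 9 of 26 members higher over all genes and 13 higher and 1 lower when adjusted over the list alone. It had adjusted p = 0.0702 with an estimated correlation. Its members were led by rps27l (2.02 ± 0.22), the growth-arrest gene gadd45b (ENSDARG00000027744, 0.87 ± 0.11), and by the antiproliferative gene btg2 (1.39 ± 0.19). On 15 libraries 16 rose and 1 fell, with adjusted p = 0.00825 with an estimated correlation. The integrated and mitochondrial stress response rose as a list (fry adjusted p = 0.00329, median 0.14), with 7 of 39 members higher over all genes, 11 higher and 1 lower when adjusted over the list alone. It had adjusted p = 0.128 with an estimated correlation. Its leading members were trib3, the transcription factor gene cebpb (0.86 ± 0.10) and mthfd1l, an enzyme of mitochondrial folate metabolism (2.12 ± 0.27). On 15 libraries 14 rose and 1 fell, with adjusted p = 0.0317 with an estimated correlation. Immediate early genes rose as a list (fry adjusted p = 0.00240, median 0.61), with 12 of 32 members higher over all genes, 15 higher and 1 lower when adjusted over the list alone. It had adjusted p = 0.0934 with an estimated correlation. They were led by atf3, the AP-1 subunit gene fosl1 (2.38 ± 0.26) and the phosphatase gene dusp1 (1.47 ± 0.19). On 15 libraries 13 rose and 1 fell, with adjusted p = 0.203 with an estimated correlation. The heat shock response (median −0.17, fry adjusted p = 0.452), the oxidative stress response (−0.16, 0.452) and the unfolded protein response of the endoplasmic reticulum (−0.04, 0.588) did not pass.

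Of 4 lists of immune transcripts 3 rose, and neutrophil and mast cell markers did not pass (0 of 13 members, median 0.09, fry adjusted p = 0.930). The interferon response rose as a list (fry adjusted p = 0.00275, median log2 fold change 0.71), with 8 of 35 members higher over all genes, 19 higher and 1 lower when adjusted over the list alone. It had adjusted p = 0.0934 with an estimated correlation. Beside isg15 its members included the interferon regulatory factor irf3 (1.42 ± 0.26). In the fit on 15 libraries 19 members rose, with adjusted p = 0.0341 with an estimated correlation. Microglia and macrophage markers rose as a list (fry adjusted p = 0.00834, median 0.64), with 9 of 41 members higher over all genes, 22 when adjusted over the list alone and adjusted p = 0.128 with an estimated correlation. The leading members were the chemokine gene cxcl18b (2.26 ± 0.33), the tumour necrosis factor gene tnfb (from 0.877 to 2.63 normalized CPM) and the galectin gene lgals9l1 (1.17 ± 0.19). On 15 libraries 27 members rose, with adjusted p = 0.0854 with an estimated correlation. Lymphocyte markers rose as a list (fry adjusted p = 0.00592, median 0.72), with 2 of 19 members higher over all genes, 6 when adjusted over the list alone and adjusted p = 0.143 with an estimated correlation. The 2 members were the chemokine receptor gene ccr9 (ENSDARG00000055186, 2.17 ± 0.27) and the T cell kinase gene lck (1.44 ± 0.31), and of these lck did not pass without the family block (adjusted p = 0.150). The next member, zap70, was at 0.64 ± 0.17 and did not pass (adjusted p = 0.0859). In the fit on 15 libraries 5 lymphocyte members rose, with adjusted p = 0.0872 with an estimated correlation.

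**Figure D3:**
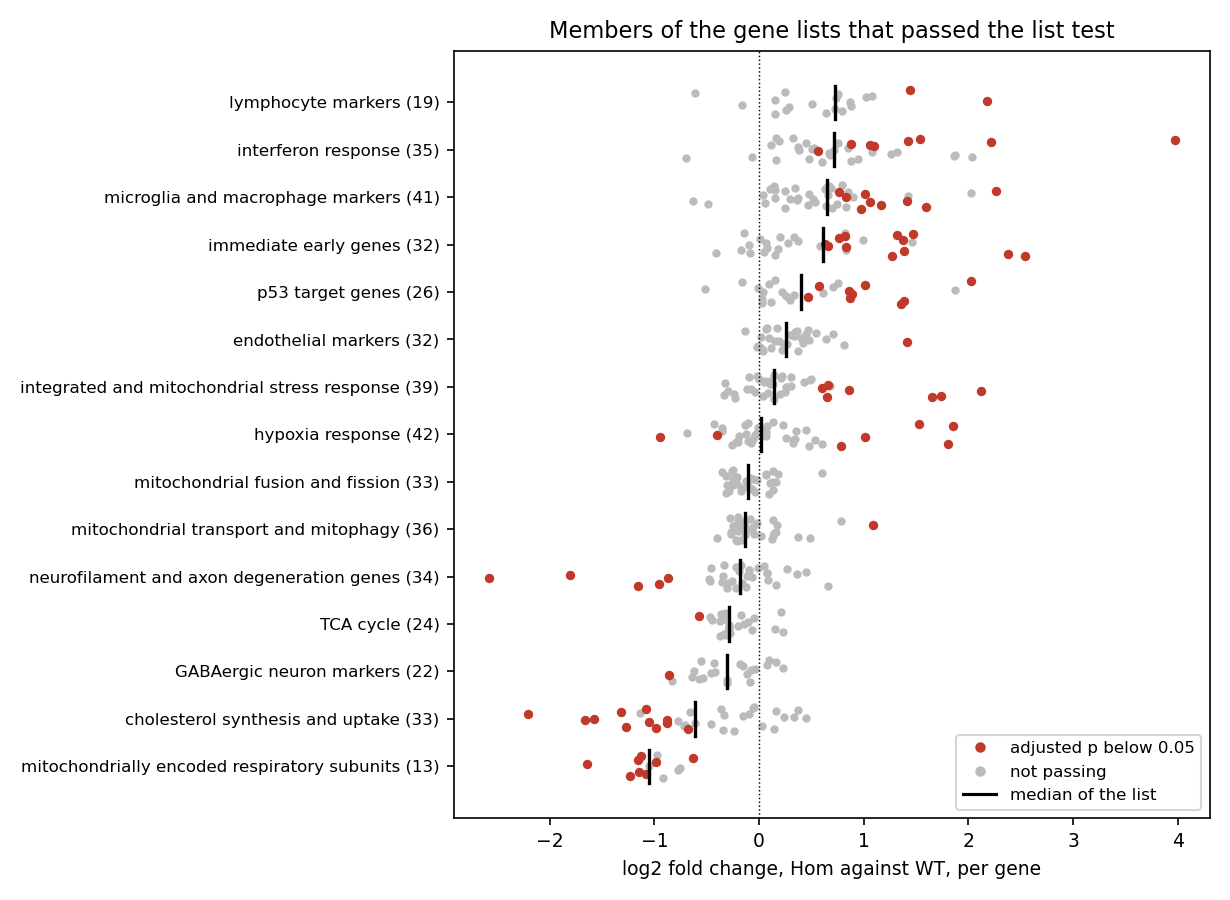
Log2 fold change, Hom against WT, of each member of the 15 lists that passed the fry test, with the number of tested members after each name, red points for genes past the gene test and a black line at the median. Medians run from −1.06 for the mitochondrially encoded subunits to 0.72 for the lymphocyte markers.

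5 further lists passed the fry test with few members past the gene test. Endothelial markers rose as a list (fry adjusted p = 0.00329, median log2 fold change 0.26), with 1 of 32 members higher over all genes and 1 when adjusted over the list alone, and adjusted p = 0.0934 with an estimated correlation. That member was plvapb, which encodes a protein of fenestrated vessels (1.41 ± 0.28), and ecscr (0.54 ± 0.18) and sox7 (0.27 ± 0.09) did not pass. On 15 libraries 5 endothelial members rose over all genes and 9 when adjusted over the list alone. The TCA cycle fell as a list (fry adjusted p = 0.0101, median −0.28), with 1 of 24 members lower over all genes and 1 when adjusted over the list alone, and adjusted p = 0.128 with an estimated correlation. That member was the succinate dehydrogenase subunit gene sdhd (ENSDARG00000055712, −0.57 ± 0.13). It did not pass without the family block (adjusted p = 0.130), and sdhb (−0.36 ± 0.12) did not pass. On 15 libraries 9 TCA cycle members fell over all genes and 18 when adjusted over the list alone. Mitochondrial transport and mitophagy fell as a list (fry adjusted p = 0.0247, median −0.13). Its only member past the test, 1 of 36 over all genes and when adjusted over the list alone, was the autophagy receptor gene sqstm1, which rose (1.09 ± 0.17). Members phb2 (ENSDARG00000017728, −0.40 ± 0.13) and trak2 (0.79 ± 0.30) did not pass, and on 15 libraries 2 members rose and 2 fell, over all genes and over the list alone. Its call was lost without the family block (fry adjusted p = 0.0660) and gave adjusted p = 0.143 with an estimated correlation. Mitochondrial fusion and fission genes, mfn2 not among them, fell as a list (fry adjusted p = 0.0339, median −0.10) with 0 of 33 members past edgeR's quasi-likelihood test over all genes and 0 when adjusted over the list alone. The members of smallest p were the protease gene yme1l1 (ENSDARG00000104401, −0.25 ± 0.07, unadjusted p = 0.00481), the fission GTPase gene dnm1l (−0.28 ± 0.09, 0.00581) and mffb (−0.31 ± 0.11, 0.0192). On 15 libraries 5 fell over all genes, and 10 fell and 1 rose when adjusted over the list alone. The call of this list was lost without the family block (fry adjusted p = 0.0660) and gave adjusted p = 0.158 with an estimated correlation. The hypoxia response rose as a list (fry adjusted p = 0.0493, median 0.02), with 5 of 42 members higher and 2 lower over all genes, 8 higher and 4 lower when adjusted over the list alone. It had adjusted p = 0.553 with an estimated correlation. Beside slc2a1 it was led by the insulin-like growth factor binding protein gene igfbp1 (1.86 ± 0.20) and the hexokinase gene hk2 (1.53 ± 0.19). On 15 libraries 8 of 43 members rose and 4 fell over all genes, and 11 rose and 6 fell when adjusted over the list alone. The hypoxia call was lost without the family block (fry adjusted p = 0.0527).

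Sibling groups chosen by genotype at mfn2 also share parental alleles of its neighbours, so the chromosome of mfn2 was compared with the others. On chromosome 8, with mfn2 itself left out, 26 of 865 tested genes (3.01%) passed for Hom against WT. Elsewhere 363 of 19487 (1.86%) passed. The adjustment over 3 comparisons counted Het against WT, where 0 genes were called and the test could not pass. The odds ratio of 1.63 did not pass Fisher's exact test after this adjustment (p = 0.0217, adjusted p = 0.0652). It did pass without the 3 libraries, with 101 of 869 genes against 1556 of 19716 (odds ratio 1.53, Fisher's exact test adjusted p = 4.89e-04), where chromosome 8 ranked 1 of 25 by odds ratio, against 3 of 25 with all libraries. The 5 changed genes nearest to mfn2 were pimr185 (log2 fold change 2.05 ± 0.38), si:ch211-220m6.5 (2.62 ± 0.49), si:ch211-163b2.2 (−1.58 ± 0.25), si:ch73-308b14.1 (1.88 ± 0.22) and the phosphatase gene dusp2 (0.82 ± 0.14), which did not pass without the family block (adjusted p = 0.0620). With all libraries, changed genes were not more frequent within 100 rows of mfn2 (4 of 127) than farther along the chromosome (22 of 738, Fisher's exact test p = 0.785). Without the 3 libraries the counts were 19 of 128 and 82 of 741 (Fisher's exact test p = 0.232). Both fits hold family 2 as labelled, so they do not exclude an effect of linked alleles near mfn2. Of the changed genes named above, nefmb, tspan36 and cebpb also lie on chromosome 8, so an effect of linked parental alleles on them was not separated from that of mfn2.

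In brains with 1 mutant copy, no gene passed the test in the model with genotype and family, mfn2 included. The level of mfn2 was lower in Het by a log2 fold change of −0.54 ± 0.16, lower in 5 of 6 families, and this did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (unadjusted p = 0.00612, adjusted p = 0.903). Without the 3 libraries and family 2, whose libraries labelled WT and Het go against their labels, it was −0.68 and passed (adjusted p = 0.0117), as did ENSDARG00000096449, 37 rows from mfn2 on the same chromosome. Family 2 was left out for its mfn2 levels, so this choice favours a pass and is no independent test. Of 20353 genes, 0 passed edgeR's quasi-likelihood test for Het against WT, with 524 at an unadjusted p below 0.05, 0 by limma-voom and 2 by DESeq2. On 15 libraries edgeR's test gave 0 as well, with 582 at an unadjusted p below 0.05. The genes of smallest p, none of which passed, were si:ch211-209m20.7 (2.50 ± 0.37, unadjusted p = 1.45e-05), ENSDARG00000097234 (1.11 ± 0.24), msnb (−1.61 ± 0.36), the gut and pancreas peptide gene pyy (−2.74 ± 0.62) and mst1 (−1.06 ± 0.25). DESeq2 called the first of these (adjusted p = 0.00186) and pyy (adjusted p = 0.00692). The level of si:ch211-209m20.7 was 5.23 normalized CPM in the Het library of family 3, which stands apart, against 0.316 to 0.649 in the other 5 Het libraries.

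Of the 44 lists, 0 passed the fry test for Het against WT, with a lowest adjusted p of 0.913, 0 passed fry on 15 libraries, and 14 passed camera with its preset correlation and 0 with an estimated correlation. Median, mean and test differed in sign for 7 lists: cholesterol synthesis and uptake, contacts of endoplasmic reticulum and mitochondria, lysosome and autophagy, mitochondrial fusion and fission, mitochondrial transport and mitophagy, neurofilament and axon genes, and the TCA cycle. On chromosome 8, 5 of 865 genes had an unadjusted p below 0.01 against 48 of 19487 elsewhere (odds ratio 2.35, Fisher's exact test adjusted p = 0.111). Without the 3 libraries and family 2, a choice made after the data were seen, the counts were 23 of 879 and 86 of 19910 (odds ratio 6.19, Fisher's exact test adjusted p = 4.14e-10). Family 2 was left out for its mfn2 levels, and genes near mfn2 went against the labels there too. The choice therefore favours this outcome.

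Hom brains were also compared with Het brains, a comparison that shares the 6 Hom libraries with the one against WT. The raised genes of smallest p were atf3 (log2 fold change 2.39 ± 0.16), slc2a1 (ENSDARG00000007412, 1.85 ± 0.14), isg15 (3.38 ± 0.27), mych (2.13 ± 0.18), the protease gene adamts8 (ENSDARG00000007709, 3.14 ± 0.30), trib3 (from 13.3 to 37.3 normalized CPM), tgm2l (2.24 ± 0.23), tspan36 (1.36 ± 0.15), ush1c (from 0.550 to 2.54 normalized CPM) and the intermediate filament gene nes (1.73 ± 0.19). The lowered genes included nefla (−1.89 ± 0.13), tmprss4b (−1.68 ± 0.15), nefmb (−2.72 ± 0.24), fxyd7 of the sodium pump regulators (−1.09 ± 0.11), eef1a2 (−1.17 ± 0.12), lss (−1.72 ± 0.18), mfn2 (−1.52 ± 0.17), the sterol desaturase gene sc5d (−1.39 ± 0.16) and cyp51a1 (−1.52 ± 0.17). Each moved the same way in 6 of 6 families, and adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 2.71e-05 to 5.97e-04.

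In all, 406 genes passed for Hom against Het, 243 higher and 163 lower in Hom, and 981 passed without the 3 libraries, 604 higher and 377 lower, with 347 of the 406 among them. Leaving out a family gave 169 (family 1), 178 (2), 645 (3), 127 (4), 135 (5) and 208 (6) genes. Leaving out a library moved the count by more than 1.5 times for Het of family 1 (218), 4 (195) and 5 (215), and for Hom of family 1 (203), 3 (662), 4 (197), 5 (227) and 6 (247). It did so too for the libraries labelled WT (262) and Het (230) of family 2 and for WT of family 4 (255) and 5 (262). With DESeq2 1626 genes passed, 789 higher and 837 lower, and the share of higher genes was 48.5% against 59.9%. On chromosome 8, 20 of 865 genes passed, against 385 of 19487 elsewhere (odds ratio 1.17, Fisher's exact test adjusted p = 0.683), and chromosome 8 ranked 7 of 25, or 11 of 25 without the 3 libraries. The 5 changed genes nearest to mfn2 were msmbl (−2.12 ± 0.47), si:ch211-163b2.2 (−1.31 ± 0.25), si:ch73-308b14.1 (1.06 ± 0.22), arid5a (1.17 ± 0.26) and dusp2 (0.91 ± 0.15), of which msmbl (adjusted p = 0.0724) and si:ch73-308b14.1 (adjusted p = 0.136) did not pass without the family block.

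For Hom against Het 16 lists passed the fry test, 6 higher and 10 lower in Hom, 0 passed with an estimated correlation (lowest adjusted p = 0.268), and 9 passed without the family block. On 15 libraries 13 passed fry, 6 higher and 7 lower, among them pan-neuronal (fry adjusted p = 0.00232) and lymphocyte markers (0.0153), which did not pass with all libraries. With an estimated correlation 5 lists passed on 15 libraries, and neither of these was among them. Leaving out a family gave 13 (family 1), 5 (2), 22 (3), 6 (4), 8 (5) and 11 (6) lists. Cholesterol genes fell with 14 of 33 members lower over all genes and 20 when adjusted over the list alone, and neurofilament and axon genes with 6 of 34 and 11 when adjusted over the list alone (fry adjusted p = 0.00113 for both, adjusted p = 0.268 with an estimated correlation for both). Mitochondrially encoded subunits fell with 11 of 13 members lower over all genes and 13 when adjusted over the list alone (fry adjusted p = 0.00160, adjusted p = 0.268 with an estimated correlation), led by mt-nd3 (−1.72 ± 0.23), mt-nd2 (−1.27 ± 0.18) and mt-co1 (−1.24 ± 0.18). GABAergic markers fell with 2 of 22 members and 5 when adjusted over the list alone (fry adjusted p = 0.00872, adjusted p = 0.268 with an estimated correlation), namely calb2b (from 74.6 to 37.9 normalized CPM) and calb2 (−0.56 ± 0.11) over all genes, while gad1 (ENSDARG00000027419) was at −0.32 ± 0.08 and did not pass. On 15 libraries the members lower over all genes were 15 of 33 for cholesterol, 11 of 34 for neurofilaments and axons, 13 of 13 for mitochondrially encoded subunits and 5 of 23 for GABAergic markers.

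Among the lists that rose, p53 targets had 8 of 26 members higher and 1 lower over all genes and 11 higher and 1 lower when adjusted over the list alone (fry adjusted p = 0.00160, adjusted p = 0.283 with an estimated correlation), led by rps27l (2.02 ± 0.22), gadd45b (ENSDARG00000013576, 1.29 ± 0.19) and gadd45a (ENSDARG00000043581, 0.82 ± 0.14). Endothelial markers had 1 of 32 and 1 when adjusted over the list alone (fry adjusted p = 0.00808, adjusted p = 0.283 with an estimated correlation), with plvapb at 1.25 ± 0.28 and with slc16a1 (ENSDARG00000068572, 1.01 ± 0.32) and mmrn2b (0.66 ± 0.22) not passing. Immediate early genes had 6 of 32 higher over all genes and 10 higher and 1 lower when adjusted over the list alone (fry adjusted p = 0.00833, adjusted p = 0.323 with an estimated correlation), with fosl1 at 2.28 ± 0.26. The stress response list had 5 of 39 and 9 when adjusted over the list alone (fry adjusted p = 0.0114, adjusted p = 0.323 with an estimated correlation), with mthfd1l from 1.07 to 4.67 normalized CPM and sesn2, a gene induced by stress, at 0.75 ± 0.12. The interferon response had 5 of 35 higher over all genes and 11 higher and 1 lower when adjusted over the list alone (fry adjusted p = 0.0164, adjusted p = 0.323 with an estimated correlation), with dhx58 at 1.82 ± 0.32 and irf3 at 1.36 ± 0.26. Microglia and macrophage markers had 5 of 41 and 14 when adjusted over the list alone (fry adjusted p = 0.0310, adjusted p = 0.323 with an estimated correlation), with cxcl18b at 2.17 ± 0.34, tnfb at 1.54 ± 0.26 and the scavenger receptor gene marco at 0.90 ± 0.17. On 15 libraries the members higher over all genes were 13 for p53 targets (1 lower), 3 endothelial, 9 immediate early (1 lower), 11 of the stress response list, 17 interferon and 21 microglia and macrophage. Without the family block 7 calls were lost: interferon (fry adjusted p = 0.0606), microglia (0.0531), mitochondrial transport (0.0730), complexes II and III (0.0730), skeletal muscle (0.135), mitochondrial ribosomal proteins (0.0539) and fusion and fission (0.0554).

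The 6 other lists fell with few members past the gene test, each with adjusted p from 0.283 to 0.323 with an estimated correlation. They were the TCA cycle (fry adjusted p = 0.0127, median −0.29, 0 of 24 over all genes and 15 when adjusted over the list alone), mitochondrial transport and mitophagy (0.0146, median −0.19 but mean 0.00334, 1 of 36 higher over all genes, sqstm1 at 1.14 ± 0.17, and 2 higher and 3 lower when adjusted over the list alone) and mitochondrial fusion and fission (0.0448, 0 of 33 and 3 when adjusted over the list alone). Subunits of complexes II and III (0.0421, 0 of 14 and 11 when adjusted over the list alone) and mitochondrial ribosomal proteins (0.0421, 0 of 75 and 25 when adjusted over the list alone) fell too. None of these lists' other named members passed, among them sdhd (ENSDARG00000055712, −0.43; ENSDARG00000030139, −0.41), pdha1a (−0.39), phb2 (ENSDARG00000017728, −0.48), trak2 (1.06), uqcrfs1 (−0.50), uqcrh (−0.51), mrps34 (−0.50), mrps23 (−0.46), mrpl33 (−0.36), mffb (−0.46), yme1l1 (ENSDARG00000104401, −0.30) and dnm1l (−0.30). Skeletal muscle markers fell (0.0421), with 1 of 34 members over all genes and 1 when adjusted over the list alone, ttn (ENSDARG00000000563, −1.98 ± 0.34), while atp2a1 (−4.11 ± 1.23) and acta1 (ENSDARG00000055618, −1.70 ± 0.54) did not pass. Without the family block ttn did not pass (adjusted p = 0.0783), and atp2a1 (adjusted p = 0.0358) and yme1l1 (ENSDARG00000104401, adjusted p = 0.0441) did. The Het library of family 3, which stands apart, held 82.0 normalized CPM of ttn against 10.3 to 21.9 in the other 5 Het libraries, and without the 3 libraries the muscle list did not pass (fry adjusted p = 0.196). Without them 4 further lists did not pass: immediate early genes (fry adjusted p = 0.0797), complexes II and III (0.105), mitochondrial ribosomal proteins (0.113) and fusion and fission (0.0504). On 15 libraries 4 TCA cycle members, 2 of complexes II and III, 1 mitochondrial ribosomal protein and 1 fusion and fission member fell over all genes, 2 of mitochondrial transport and mitophagy rose, and of muscle markers 1 rose and 1 fell.

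Fold changes of Het and of Hom against the shared WT libraries were compared across genes, which are not independent replicates. Their correlation was r = 0.11 with a covariance of 0.0147. In 20 simulations of unchanged groups with shared WT libraries the averages were r = 0.50 and a covariance of 0.0457. The simulations drew each gene and library independently, so they lacked the deviations shared by the 3 libraries that stand apart. They therefore do not decide what the lower r means. The rank correlation was −0.07 and 42.3% of genes had the same sign, against 0.46 and 66.6% simulated, and at a mean CPM of at least 1 r was 0.00865 and the rank correlation −0.15. Without the 3 libraries r was 0.29 and the covariance 0.0333, against 0.45 and 0.0263 simulated, and without family 2 as well they were 0.37 and 0.0618, against 0.44 and 0.0338. Each arm was also set against WT of its own families. Het from families 1 to 3 with Hom from families 4 to 6 gave r of 0.00241, and the reverse 0.14. Families 1 to 3 hold all 3 libraries that stand apart and the libraries of family 2 that go against their labels. Leaving out a family gave r of 0.18 (family 1), 0.12 (2), 0.36 (3), 0.11 (4), 0.00228 (5) and 0.04 (6). With 0 calls in Het by edgeR's quasi-likelihood test, 524 at an unadjusted p below 0.05 and 2 by DESeq2, an overlap of calls could not be tested. Without the 3 libraries and family 2, 2 genes were called in both comparisons, against a mean of 0.2 simulated. These were mfn2 itself and ENSDARG00000096449, 37 rows from it on the same chromosome and among the 18 genes near mfn2 used below for family 2. The overlap therefore does not show a shared response beyond that chromosome.

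Families, each from its own parents, differed in 389 genes (1.91%) past edgeR's quasi-likelihood test of the family terms, and in 2207 (10.7%) without the 3 libraries.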

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

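Of the tests below, those of chance variation in family 2, of oocyte transcripts, of other tissue, of a shared technical trend, of the label of the Hom library of family 3, of plain CPM and of the 3 libraries as the source of the lower mitochondrial transcripts were chosen after the result was seen. A library is listed where its distance to the nearest of its group of 6 took more than 0.625 of the group's range (Dixon's critical value). For independent groups of normally distributed values, chance gives about 1 such library in 20 groups, so 13.5 among the 270 groups tested. In all, 44 were found, 13 of them in the Hom library of family 3. The groups share the same libraries and are not independent, so the 13.5 does not test the 44.

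Total counts were 42.9 M (42897654) in the library labelled WT of family 2, against 25.9 M to 30.4 M in the other WT libraries. The mitochondrially encoded share in the Hom library of family 3 was 1.93%, against 5.18% to 6.19% in the other Hom libraries. Its SD of log2 deviations was 1.06, against 0.183 to 0.275, and its sum over the oocyte list was 246 CPM, against 11.7 to 17.4.

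In family 2 the level of mfn2 was higher in the library labelled Het than in the library labelled WT. Variation between pools is argued against, since the log2 ratio of Het to WT lay 10.3 SDs from the mean of the other 5 families. An exchange of these 2 libraries may explain the pattern: over 18 genes near mfn2, the position of WT minus that of Het was 0.298 in family 2, and the highest in another family was −0.479. Parents that differ between families would still place Het between its WT and Hom siblings where both copies add up. Positions ran from 0, the mean of the other WT libraries, to 1, that of the other Hom libraries. Family 2 had medians of 0.429 in WT, −0.0708 in Het and 0.835 in Hom. WT lay nearer Hom than Het did in 13 of the 18 genes. In every other family the median of Het lay between its siblings. For these genes this argues against parents alone. No other biological explanation was tested. Which fish each library came from cannot be read from the counts, so groups were kept as labelled.

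The Het libraries of families 1 and 3 and the Hom library of family 3 deviated widely from all others. A wrong genotype of the Hom library is argued against, since its mfn2 level of 26.5 normalized CPM lay below the highest other Hom level of 34.1. Oocyte transcripts, at 14.1 times the highest other library, are consistent with egg tissue in that pool. Whether other tissue made its deviations wide stays open. Its median log2 deviation was −0.00138 over 26 pan-neuronal members (SD 1.21) and −0.85 over 24 myelin members (SD 1.43). The difference of 0.849 thus came from myelin genes, with members of both lists going both ways. A technical trend may be shared by the 3 libraries, whose deviations ran opposite with r = −0.65 across genotypes. Pairs among the other libraries lay between −0.33 and 0.67, and pairs of the 3 with the others were not summarized. No biological explanation was tested.

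Mitochondrially encoded transcripts were lower in Hom than in WT. The tables argue against the 3 libraries as the source, since the median log2 fold change was −0.83 without them. They argue too against a general loss of neurons of that size, since the pan-neuronal median was −0.15 with an SD of 0.20 over its members. That list passed the fry test as lowered without the 3 libraries, so a smaller loss or a loss of some neurons stays open. Counts taken by a few abundant genes would lower the others alike, and this is argued against, since on plain CPM the median log2 difference of 11307 other genes was 0.0856 ± 0.0236 (SD, 5 families). Scaling on nuclear genes left −0.83 but moved the median of all genes only from 0.0164 to 0.0121, so it decides nothing. Degradation of RNA and the tank, which differed with genotype, were not tested and stay open, as does an effect of mfn2. GC content and gene length bias could not be tested without sequence of the build.

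Other groupings of the same libraries gave few calls for both comparisons with Hom. Of 100 random splits, the real one included, 1 gave as many genes for Hom against WT (390 genes, highest other 0) and 1 for Hom against Het (406 genes, highest other 3). Most of the other random splits put both libraries of some families in the same group, which weakens them under the family block. Of the 32 splits that swap labels within families, 1 gave as many for each, with a highest other of 2. These swaps part every family, and 1 in 32 is the smallest share they allow. Chance is therefore argued against but not excluded. For Het against WT, 0 genes passed edgeR's quasi-likelihood test, with 524 at an unadjusted p below 0.05, 0 by limma-voom and 2 by DESeq2. No split can give fewer than 0, so the 100 random splits and 32 swaps, with a highest other of 1 in each, do not test this comparison.

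Normalized CPM in the Hom library of family 3 stood apart for tmprss4b at 15.3 against 8.46 to 10.4, mt-nd3 at 122 against 423 to 508, sdhb at 109 against 193 to 217, and slc16a1 (ENSDARG00000068572) at 15.1 against 6.60 to 8.69. So did those of sdhd (ENSDARG00000030139) at 44.1 against 71.9 to 81.1, pdha1a at 158 against 258 to 283, uqcrfs1 at 113 against 220.2 to 241, and uqcrh at 95.8 against 199 to 241. So did those of ttn (ENSDARG00000000563) at 19.1 against 2.86 to 6.94 and mrps23 at 9.44 against 15.4 to 18.9. Normalized CPM in the Het library of family 1 stood apart for mt-nd3 at 1557 against 1173 to 1275, lck at 3.66 against 0.480 to 1.31, lgals9l1 at 80.0 against 29.0 to 46.0, and yme1l1 (ENSDARG00000104401) at 57.8 against 49.1 to 51.9. So did those of mrpl33 at 31.7 against 18.5 to 23.0. The values of the Het library of family 3 stood apart for hk2 at 2.54 against 3.51 to 4.04, si:ch211-209m20.7 at 5.23 against 0.316 to 0.649, ttn (ENSDARG00000000563) at 82.0 against 10.3 to 21.9, and atp2a1 at 60.9 against 0.280 to 10.6. So did those of acta1 (ENSDARG00000055618) at 3.67 against 0.20 to 1.34 and msmbl at 1.56 against 0.240 to 0.573.

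Normalized CPM in the library labelled WT of family 2 stood apart for mfn2 at 75.2 against 119.9 to 140.2 and pimr185 at 1.81 against 0.235 to 0.726. Levels in the Hom library of family 1 stood apart for slc2a1 (ENSDARG00000007412) at 37.4 against 20.9 to 25.9 and ccr9 (ENSDARG00000055186) at 8.24 against 3.04 to 4.82. The values of the WT library of family 6 stood apart for mych at 13.6 against 6.11 to 8.27, trib3 at 15.5 against 10.05 to 11.7, socs3 (ENSDARG00000025428) at 22.8 against 3.41 to 7.16, and dusp1 at 24.8 against 9.77 to 13.9. So did those of igfbp1 at 22.9 against 5.29 to 9.19. Normalized CPM in the Hom library of family 2 stood apart for nefla at 250.2 against 146 to 171 and lss at 6.91 against 2.91 to 3.98. Levels in the Het library of family 4 stood apart for sqle (ENSDARG00000079946) at 5.48 against 16.1 to 22.4. The values of the library labelled Het of family 2 stood apart for sdhd (ENSDARG00000055712) at 28.9 against 38.3 to 42.2 and pyy at 1.22 against 0.344 to 0.640. Gene levels in the Het library of family 6 stood apart for igfbp1 at 18.5 against 5.02 to 8.78. Normalized CPM in the Hom library of family 6 stood apart for dusp2 at 10.002 against 6.05 to 7.24. Levels in the WT library of family 3 stood apart for si:ch211-209m20.7 at 0.402 against 0.0470 to 0.158. The values of the WT library of family 4 stood apart for mmrn2b at 1.75 against 0.808 to 1.07 and atp2a1 at 2.90 against 0.0785 to 0.587.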

How the results depend on the processing

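Settings that leave out the 3 libraries that stand apart, alone or with family 2, that weight libraries by quality or that scale on nuclear genes alone were chosen after the data were seen. The setting without the 3 libraries and family 2 drops that family for its mfn2 levels. It is therefore no independent test of mfn2 or its chromosome. All counts given here come from groups as labelled. Where a result changed, the cause was not tested, except that settings with fewer libraries or 2 genotypes also have fewer values.

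The number of genes changed for Hom against WT was 1054 with DESeq2, 202 with only the compared genotypes, 1658 without the 3 libraries, 1216 without those and family 2, 2012 with quality weights and 1697 with nuclear scaling and without the 3 libraries. Hom against Het gave 1626, 46, 981, 1411 and 999 genes with DESeq2, the compared genotypes, 15 libraries, quality weights and nuclear scaling on 15 libraries. Het against WT gave 2 genes with DESeq2 and 2 without the 3 libraries and family 2, and 0 in every other setting run. Leaving out a family or library gave 142 to 716 genes for Hom against WT and 127 to 662 for Hom against Het.

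The level of mfn2 in Het against WT, −0.54 with all libraries, was −0.68 and passed without the 3 libraries and family 2. On chromosome 8 the odds ratio for Hom against WT passed at 1.73 without the family block, 1.71 with DESeq2, 1.76 with limma-voom, 1.53 without the 3 libraries, 1.96 without those and family 2, 1.45 with quality weights and 1.49 with nuclear scaling on 15 libraries. It passed too for genes at an unadjusted p below 0.01, at 1.82 and, without the 3 libraries and family 2, 1.74. For Hom against Het it fell below 1 with DESeq2 (0.950), a mean CPM of at least 1 (0.929), 15 libraries (0.990), quality weights (0.909), nuclear scaling on 15 libraries (0.971) and an unadjusted p below 0.01 (0.968, and 0.918 without the 3 libraries and family 2). Leaving out a family or library gave 1.39 to 2.31 for Hom against WT, and it passed without family 3 (1.62) or 4 (2.31), the library labelled WT of family 2 (2.09), Het of family 3 (1.61) and Hom of family 3 (1.81).

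Of 44 lists, camera with a preset correlation called 30 for Hom against WT, 14 for Het against WT and 25 for Hom against Het. With an estimated correlation it called 0 in each, and on 15 libraries 5 for Hom against WT and 5 for Hom against Het. Hom against Het gave 9 lists without the family block, 8 without the 3 libraries and family 2, and 5 to 22 with a family left out. For Hom against WT, 3 of the 15 list calls were lost without the family block and 2 without the 3 libraries and family 2. With a family left out 10 of 90 were lost. Without the block 341 genes passed for Hom against WT, 295 of them among the 390, and 423 for Hom against Het, 322 of them among the 406.

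The log2 difference in mitochondrially encoded share for Hom against WT was −0.74 without the 3 libraries and −0.78 without those and family 2, and for Hom against Het −0.72 and −0.75. It was −1.06 to −0.74 and −1.18 to −0.78 with a family left out, where an exact test of 5 families cannot pass. For Het against WT it turned to −0.012 without the 3 libraries and family 2. The correlation of Het and Hom fold changes was 0.29 without the 3 libraries, 0.37 without those and family 2, and 0.00228 to 0.36 with a family left out. Families differed in 2207 genes without the 3 libraries.

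Of 57 named values for Hom against WT, 57 kept direction and call with DESeq2 size factors, 57 with robust dispersion and 57 with nuclear scaling. Calls were lost for 3 of 57 without the family block, 1 with only the compared genotypes and 1 with no filter, and for 29 of 342 values with a family and 30 of 1026 with a library left out. For Hom against Het, calls were lost for 21 of 60 named values with only the compared genotypes, 4 of 61 without the 3 libraries and family 2, 3 without the block, and 2 each without the 3 libraries, with nuclear scaling on 15 libraries and with no filter. It was 1 each with limma-voom and quality weights, 41 of 364 with a family and 67 of 1098 with a library left out. A correction for GC content and gene length and a share that adds mitochondrial ribosomal RNA genes were not run. Depth limits what can be seen in genes of low count.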

Other observations

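Single members of lists that did not pass also moved in Hom brains, and the genes of these paragraphs were chosen after their values were seen. The neural progenitor filament gene nes rose (log2 fold change 1.85 ± 0.19, adjusted p = 2.25e-04 from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), as did nfe2l2b of the oxidative stress response (2.36 ± 0.38) and the small heat shock protein gene hspb8 (0.89 ± 0.20). Of oligodendrocyte genes, gpr17, a marker of precursors, rose (0.88 ± 0.18) and fa2h, an enzyme of myelin lipid synthesis, fell (−0.82 ± 0.18). The neuropeptide gene gnrh3 fell (−1.51 ± 0.35, from 1.22 to 0.439 normalized CPM). Each moved the same way in 6 of 6 families against the libraries labelled WT.

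Glycolysis members went both ways in Hom against WT. The list did not pass the fry test of limma for a move on balance one way (adjusted p = 0.452). With all libraries, the glucose transporter gene slc2a1 (ENSDARG00000007412) and hk2 rose over all genes, and 3 members rose and 8 fell when adjusted over the list alone. Counts without the libraries that stand apart are not given for this list. The hexokinase gene hk1, abundant in brain, was at −0.44 ± 0.11 and did not pass over all genes (adjusted p = 0.0699).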
